A study of Mus musculus with 3 samples.

How the data were processed

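Testes of 3 mouse genotypes were profiled as single cells: Cdk2-WT, Cdk2-HET and Cdk2-Y15S, with 1 library each. The series text gives the genotypes as wild type, heterozygous and homozygous for the YS allele, and Y15S names a change of residue 15 of CDK2 from tyrosine (Y) to serine (S), a site whose phosphorylation inhibits the kinase. Per the labels, the males were at postnatal day 3 on a mixed FVB/NJ with B6(Cg)-Tyrc-2J/J background, and the protocol gives 3.5 days for the dissection. The cells were released with trypsin, EDTA and DNase I, and polyadenylated RNA was read with 10x Genomics 3-prime version 2 chemistry. Per the submitters' processing notes, Cell Ranger 2.1.0, Seurat and the build mm10 were used; the role of each, the gene annotation and the calling of cells are not given in the sources used here.

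The deposited matrix holds counts, as whole unique molecular identifiers (UMIs) for 27998 genes in the cells of all 3 libraries, and the authors gave the library of each cell by its barcode. The deposited germ cell table also holds counts, for 10451 genes in 141 cells of Cdk2-WT and Cdk2-Y15S, and these equal the matrix. The authors assigned each of the 141 cells to 1 of 5 clusters, A to E. How these cells were chosen and clustered is not given in the sources used here, and the heterozygote is not among them. Gene positions were taken from GENCODE M21 on GRCm38, in which 27722 of the 27998 identifiers were found.

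The Cdk2-WT library held 5061 cells and 30624473 UMIs (median 5570 UMIs and 2190 genes per cell). Cdk2-HET held 4958 cells and 32025077 UMIs (median 5908 and 2300), and Cdk2-Y15S 4403 cells and 28651691 UMIs (median 5723 and 2223). Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept, and doublets called by Scrublet in each library (80, 93 and 64 cells, at an expected rate of 6%) were left out. This left 4767, 4751 and 4180 cells. They were clustered together without integration (log of UMIs scaled to 10000 per cell, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1). The mitochondrial limit removed many of the authors' own germ cells: 82 of the 141 lie above 10%, and 57 of the 141 were kept. Above the limit lie 45 of 69 Cdk2-WT and 37 of 72 Cdk2-Y15S germ cells, so the loss differs by library.

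Clusters were named from 13 marker lists of 5 to 10 genes. A cluster took the name of the list with the highest median log2 fold over all other cells (at least 0.5, with 10 CPM added) when at least 3 of its markers were that much higher and no other list had more markers among its top 10 genes. A hemoglobin cluster with a marker of another list in its top 10 stayed unnamed, and so would a cluster under 0.333 times the median depth of its libraries with none of its own markers there, which no cluster of the reported clustering was. Sertoli cell-like, interstitial stromal, peritubular myoid, germ, fetal Leydig, endothelial, macrophage and pericyte clusters were named. The lymphocyte, erythroid, rete or epididymal epithelium, surface epithelium and mast cell lists named no cluster under these settings.

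For each library and cell class the UMIs were summed, and each gene is given as CPM, its UMIs per summed UMIs of the class on the usual scale, with exact 95% Poisson intervals. Ratios are log2 with 0.5 UMI added to each sum, with intervals from the conditional exact binomial, and shares of cells have exact Clopper-Pearson intervals. All intervals cover counting error only. For 0 counts the limit that 3 counts would give is printed. With 1 library per genotype there is no test of genotype, no replicate check and no p-value, and each difference describes these libraries.

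Gene lists, 17 in all and fixed with the other choices before the data were examined, hold 12 to 24 members. They cover undifferentiated and differentiating spermatogonia, the piRNA pathway with de novo DNA methylation, pluripotency and primordial germ cells, meiotic prophase, S phase, G2 and M phase, CDK2 regulators, and p53 targets. The others are immediate early and heat shock genes, mitochondrially encoded genes, glycolysis, Sertoli niche and hormone genes, steroidogenesis, cholesterol biosynthesis, extracellular matrix and retinoid signalling. The value of a list is the median log2 ratio of its members with at least 20 UMIs. Its interval comes from 1000 Poisson redraws and its percentile from 10000 random lists of the same size matched on mean CPM in 20 bins. The genes Dnmt3c, Majin, Terb1, Terb2 and Trbc2 have no entry in the gene names read.

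Genes were named by a fixed rule: Cdk2, the 2 highest and 2 lowest members of each list, the 10 highest and 10 lowest germ cell ratios among genes with at least 100 UMIs, and the same among genes at least 3-fold higher in germ cells than in all other cells. In somatic classes with at least 200 cells in each library, the 5 highest and 5 lowest ratios among genes with at least 200 UMIs were listed, of which at most 3 each way are named here. Genes with at least 200 UMIs in every such class and at least 2-fold apart the same way in all of them complete the rule. Other genes are marked as chosen after their values were seen. Some genes that the rule names are not reported here. Ribosomal protein and histone genes have near-identical copies, so their counts are uncertain.

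Alternatives covered the cell filter, doublets, resolution, germ cells by markers, scaling, weighting of cells and clusters, thinning to equal depth, subtraction of 10% ambient RNA, the UMI minimum and the added UMIs. Further alternatives, chosen after the data were seen, left out chromosome 2, each other autosome or single genes from the clustering, rebuilt the germ cells under a loose filter (at least 200 genes and at most 20% mitochondrial UMIs), and counted an unnamed cluster as Sertoli cell-like. On simulated counts, planted 2-fold and 4-fold increases gave intervals off 0 for 100% of the genes and planted decreases for 98% and 100%, against 4.52% of 4160 genes with none planted. A planted 2-fold list gave a median of 1.04, and 0 of the 16 other lists had an interval off 0. Both libraries were drawn as Poisson counts from 1 pooled profile, which is what the intervals assume. These rates therefore check the computation and do not measure errors from spread between real cells, animals or libraries. Naming was right for 100% of 500 simulated cells of 5 classes. These cells were drawn at equal depth, without spread inside a class, from the summed profiles of classes already named by the same rule. The value therefore does not measure how well real cells are named. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.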

Results

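The series asks how the kinase activity of CDK2 bears on the fate of male germ cells. In the neonatal testis, germ cells leave a quiescent prospermatogonial state, re-enter the cell cycle, and give rise both to undifferentiated spermatogonia, from which stem cells are drawn, and to spermatogonia that differentiate. Libraries of wild type, heterozygous and homozygous Y15S testes are compared here.

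The germ cells of Cdk2-WT and Cdk2-Y15S fell largely into different clusters of the authors' assignment. Cluster A held 36 of 69 Cdk2-WT germ cells (52.2%, 39.8 to 64.4) and 0 of 72 of Cdk2-Y15S, which allows a share of up to 4.17%. Clusters D and E held 37 (51.4%, 39.3 to 63.4) and 21 (29.2%, 19.05 to 41.1) of the 72 Cdk2-Y15S germ cells and 0 of the 69 of Cdk2-WT, which allows up to 4.35%. Both libraries were present in cluster B, with 28 Cdk2-WT cells (40.6%, 28.9 to 53.1) and 6 of Cdk2-Y15S (8.33%), and in cluster C, with 5 (7.25%) and 8 (11.1%). Together, 94 germ cells (66.7%, 58.2 to 74.4) sat in clusters at least 90% of 1 library. A cluster mostly of 1 library may be that library and not a type.

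**Figure D1:**
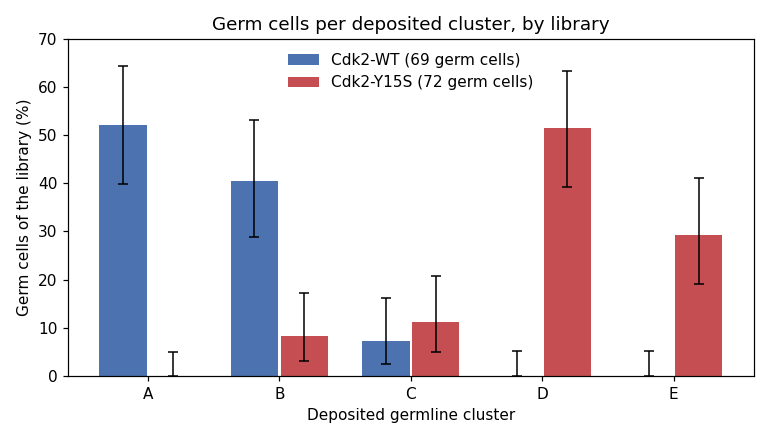
Percent of the germ cells of each library (y axis) in each deposited cluster A to E (x axis), for Cdk2-WT (69 cells) and Cdk2-Y15S (72 cells). Bars are shares and lines exact 95% intervals for counting error; cluster A is at 52.2% in Cdk2-WT, and clusters D and E at 51.4% and 29.2% in Cdk2-Y15S.

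Germ cells made up a similar share of the Cdk2-WT and Cdk2-Y15S libraries. The authors' germ cells make up 1.36% (1.06 to 1.72) of Cdk2-WT cells and 1.64% (1.28 to 2.05) of Cdk2-Y15S cells. In the rebuilt clustering, germ cell-like clusters held 53 kept cells of Cdk2-WT (1.11%, 0.834 to 1.45), 34 of Cdk2-HET (0.716%, 0.496 to 0.999) and 62 of Cdk2-Y15S (1.48%, 1.14 to 1.90). Their median depths differed, at 7917, 11592.5 and 12116.5 UMIs. The authors' germ cells include 23 of the 53 Cdk2-WT and 34 of the 62 Cdk2-Y15S cells. Cells with at least 1 UMI of 2 or more of Ddx4, Dazl and Mael gave 1.17%, 0.758% and 1.51%. The heterozygote had the lowest share by either count. Under the loose filter (at least 200 genes, at most 20% mitochondrial UMIs) the shares were 2.32%, 1.26% and 2.54%, so the level depends on the filter.

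Transcripts of Cdk2 itself were present in each library. Cdk2 (ENSMUSG00000025358, chromosome 10, 128697939 to 128705031, minus strand) stood at 78.7 CPM (63.6 to 96.3) in Cdk2-WT germ cells and 99.5 (83.6 to 118) in Cdk2-Y15S germ cells, with overlapping intervals. In the rebuilt germ cell-like clusters under the loose filter it was 72.1, 94.2 and 97.7 CPM in Cdk2-WT, Cdk2-HET and Cdk2-Y15S. Sertoli cell-like cells had 50.04, 60.6 and 58.9 CPM, stromal cells 40.7, 36.5 and 33.3, and myoid cells 38.0, 34.9 and 36.1. A point mutation need not alter the level of its transcript, so these values do not test the genotype labels.

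Stra8, the retinoic acid-induced gene of differentiating spermatogonia, was far higher in Cdk2-Y15S germ cells, at 221 CPM (197 to 247) against 26.8 (18.3 to 37.8) in Cdk2-WT (log2 ratio 3.02). Bcl6b, a gene that sustains spermatogonial stem cells, was lower, at 32.5 CPM (23.7 to 43.4) against 121 (102 to 143), a log2 ratio of -1.89. At least 1 Stra8 UMI was found in 15 of 69 Cdk2-WT germ cells (21.7%, 12.7 to 33.3) and 44 of 72 Cdk2-Y15S germ cells (61.1%, 48.9 to 72.4), at median depths of 16434 and 18253.5 UMIs. In Sertoli cell-like cells, which should lack Stra8, the shares were 0.103% and 0.143% at medians of 6107.5 and 6333 UMIs. Bcl6b was found in 66.7% and 34.7% of the germ cells and in 0.155% and 0.0716% of the Sertoli cell-like cells. After thinning each germ cell to 13000 UMIs, which left out 9 and 8 shallower cells, Stra8 was found in 12 of 60 and 38 of 64 cells (59.4%) and Bcl6b in 58.3% and 28.1%.

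The lists of spermatogonial states showed the same contrast. Genes of differentiating spermatogonia had a median log2 ratio of 0.76 (0.58 to 0.97; percentile 100 of random lists; 9 of 10 members above 0), led by Stra8 and Dmrtb1 (5.86 CPM in Cdk2-WT and 18.03 in Cdk2-Y15S, log2 1.55). Ccnd2 (-0.41) and Rhox13 (0.14) were the lowest members. Genes of undifferentiated spermatogonia stood at -0.55 (-0.74 to -0.24; percentile 0.01; 14 of 19 below 0), with Eomes (24.3 and 5.77 CPM, log2 -2.01) and Bcl6b lowest, while Lin28a (1.08) and Nanos3 (0.85) were higher in Cdk2-Y15S, though Nanos3 reversed to -1.58 with clusters B and C weighted equally.

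Genes that mark the fetal and perinatal germ cell were lower in Cdk2-Y15S. The pluripotency and primordial germ cell list had a median of -1.34 (-1.73 to -0.67; percentile 0; 6 of 8 below 0), with Sox2 at 23.4 CPM in Cdk2-WT and 2.16 in Cdk2-Y15S (28 and 3 UMIs, log2 -3.24, interval -5.80 to -1.74) and Dppa4 at 126 and 36.1 (log2 -1.80). Pou5f1 (0.17) and Klf4 (0.13) were near 0. The size of the list median depends on the choices made: it was -0.13 among members with at least 50 UMIs, -0.38 in the rebuilt germ cell-like clusters and -0.067 with clusters B and C weighted equally. The piRNA and de novo DNA methylation list stood at -0.71 (-0.85 to -0.52; percentile 0; 13 of 17 below 0). Its lowest members were Spocd1, at 15.9 and 1.44 CPM (19 and 2 UMIs, log2 -3.18, interval -6.61 to -1.41), and Dnmt3l, at 18.4 and 2.89 (22 and 4 UMIs), both needed for methylation of retrotransposons in prospermatogonia. Pld6 (0.90, interval -0.02 to 1.96) and Mov10l1 (0.36) lay highest. With clusters B and C weighted equally the piRNA median was -0.054 and Dnmt3l reversed to 1.17. Meiotic prophase genes had a median of -0.43 (-0.55 to -0.24; percentile 0.91; -0.17 in the rebuilt clusters and -0.19 with B and C weighted equally), from Meioc (-2.48) and Dmc1 (-0.997) to Syce2 (0.34) and Hormad2 (0.35).

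Mitotic genes were higher in the Cdk2-Y15S germ cells taken as a whole, but not with clusters B and C weighted equally, where G2 and M phase genes (-0.30), Aurkb (-0.19), Ube2c (-0.22), p53 targets (0.41), Zmat3 (0.76), Cdk6 (-0.37) and Cdkn1a (0.63) reversed and S phase stood at 0.016. The G2 and M phase list had a median of 0.54 (0.44 to 0.66; percentile 100; 20 of 22 above 0), with Aurkb (23.4 and 59.1 CPM, log2 1.32) and Ube2c (141.4 and 323, log2 1.19) highest and Nusap1 (-0.05) and Bub1 (-0.02) lowest. The S phase list stood at 0.23 (0.12 to 0.38; percentile 97.6; 19 of 24 above 0), with Chaf1b (0.83) and Mcm6 (0.68) above and Pcna (-1.39) and Uhrf1 (-0.28) below. CDK2 regulators as a list lay at 0.03 (-0.20 to 0.22; percentile 69.4). Among them the CDK inhibitors Cdkn1c (73.6 and 26.0 CPM, log2 -1.49) and Cdkn1a (96.2 and 36.8, log2 -1.38) were lower and Cdc25c (5.86 and 23.8, log2 1.94) and Cdk6 (0.95) higher. The p53 target list was lower, at -0.54 (-0.77 to -0.25; percentile 0.555; 11 of 15 below 0), with Zmat3 (-2.18) and the proapoptotic Pmaip1 (186 and 44.7 CPM, log2 -2.05) lowest and Bax (0.62) and Trp53 (0.35) highest.

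Of the single genes with the largest ratios among those enriched in germ cells, Lmo1 (31.8 and 196 CPM, log2 2.61), Acp5 (21.8 and 85.1, log2 1.95) and Igfbp2 (38.5 and 142, log2 1.87) were higher in Cdk2-Y15S. Aifm3 (1.59), Thop1 (1.56), Kif26a (1.47), Galnt12 (1.35) and Rangrf (1.34) followed. Over all genes with at least 100 UMIs, Tead2 (31.0 and 126 CPM, log2 2.004), Sdf2l1 (1.96), Pycard (1.90) and Galk1 (1.90) were also among the highest. The metalloproteinase gene Mmp9 was lower, at 17.3 CPM against 141.4 (log2 -3.005), as were Cxcl14 (-2.93), Cdc42ep3 (-2.71), Pcsk1n (-2.22), the heme oxygenase gene Hmox1 (233 and 49.8 CPM, log2 -2.22) and Tm4sf5 (-2.005). D15Ertd621e (-1.92) and DHRSX (-1.83) complete the germ-enriched genes, and Ly6h (-2.57), Krt18 (-2.36) and Mast4 (-1.93) are among the lowest without that limit. Rpl29 (25.9 and 521 CPM) and Gm9112 (14.2 and 91.6) were also at the top, but Rpl29 differed alike in Sertoli cell-like, stromal and myoid cells.

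**Figure D2:**
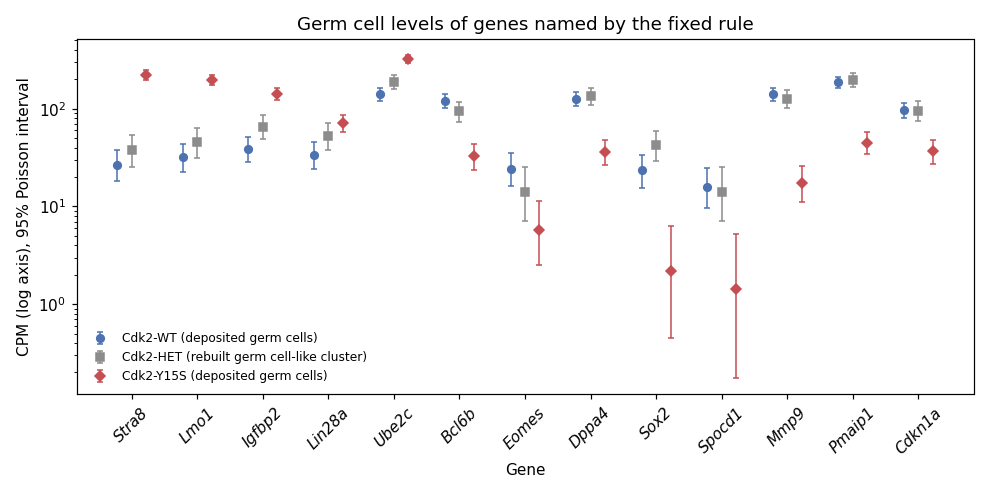
CPM on a log axis (y axis) of 13 genes named by the fixed rule (x axis) in germ cells. Points are the deposited germ cells of Cdk2-WT and Cdk2-Y15S and the rebuilt germ cell-like cells of Cdk2-HET under the loose filter, with exact 95% Poisson intervals; Stra8 stands at 26.8 CPM in Cdk2-WT, 37.4 in Cdk2-HET and 221 in Cdk2-Y15S.

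Of the remaining lists in germ cells, 2 had intervals off 0. Immediate early and heat shock genes stood at 0.21 (0.05 to 0.35; percentile 89.4), from Dusp1 (-0.98) and Egr1 (-0.64) to Nr4a1 (0.75) and Jund (0.88), and mitochondrially encoded genes at -0.11 (-0.16 to -0.04), with mt-Nd4l (-0.33) and mt-Co1 (-0.29) lowest and mt-Nd6 (0.11) highest. The sign of the mitochondrial list and of mt-Co1, Gapdh, Rxrb, Insig1, Scarb1 and Uhrf1 depended on the weighting of clusters or the choice of cells. Intervals that include 0 were found for glycolysis (-0.12, with Slc2a3 -1.20, Ldha -0.98, Eno1 0.56 and Gapdh 0.70) and for cholesterol biosynthesis (-0.18, with Hmgcs1 -1.34, Insig1 -0.91 and Msmo1 0.44). The same holds for Sertoli niche genes (-0.29, with Rhox5 -2.79, Fgf9 -2.15 and Wnt6 0.44), steroidogenesis (-0.07, with Hsd17b3 -0.60, Scarb1 0.69 and Fdxr 1.14), and retinoid signalling (-0.07, with Rxrb -0.77, Rbp4 0.86 and Cyp26b1 1.74, 4 and 17 UMIs). The extracellular matrix list stood at 0.26 (-0.04 to 0.61), and its highest member Col3a1 (1.35) reversed to -0.21 when 10% ambient RNA was subtracted.

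Clusters A and B, mostly of Cdk2-WT cells, differed from each other in cycling and in genes of the earlier germ cell state. Against all germ cells, G2 and M phase genes stood at -1.65 in cluster A and at 0.23, 0.08, 0.15 and 0.41 in clusters B, C, D and E. Cluster A also had the highest piRNA list (0.48, against 0.06, -0.21, -0.21 and -0.52) and pluripotency list (0.80, against -0.06, -0.28, -0.94 and -0.60). Differentiating spermatogonial genes were low in A and B (-0.59 and -0.57) and higher in D and E (0.29 and 0.41), while in C they were low in the 5 Cdk2-WT cells (-0.59) and higher in the 8 Cdk2-Y15S cells (0.33). Some genes show this in values that were chosen after they were seen: Mki67 at 20.6, 173, 137, 93.2 and 121 CPM from A to E, Stra8 at 25.7, 23.2, 120, 196 and 320 (in C, 28.8 in Cdk2-WT from 2 UMIs and 179 in Cdk2-Y15S), Uchl1 at 335, 296, 371, 553 and 728, Ret at 249, 150, 131, 86.8 and 35.1, and Bcl6b at 112, 115, 79.9, 35.4 and 19.5. Cluster C pools unlike libraries for some of these, with Uchl1 at 158 CPM in Cdk2-WT and 510 in Cdk2-Y15S and Bcl6b at 130 and 47.2 (9 and 5 UMIs, with overlapping intervals). Not every gene of the same lists followed: from A to E, Etv5 was at 90.9, 98.7, 74.2, 91.6 and 60.5 CPM. Gfra1 was at 158, 123, 51.3, 70.7 and 80.1, and Kit at 24.0, 43.5, 62.8, 75.6 and 50.8. Lhx1, at 115, 109, 62.8, 65.9 and 13.7, was again lowest in E. Dnmt3l was at 34.3 CPM in A and 2.90 in B, and Spocd1 at 32.6 in A and 0 UMIs in B (limit 4.35 CPM). Cluster C carried extracellular matrix genes at 1.82 above all germ cells.

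No deposited cluster holds 10 cells of both libraries, so a difference in makeup could not be separated from a difference within clusters. Weighting B and C equally leaves out A, D and E and gave 0.56 for the differentiating list, a difference found in C and not in B (-0.61 in Cdk2-WT and -0.57 in Cdk2-Y15S). It gave -0.32 for the undifferentiated list and -0.05 for the piRNA list. In cluster B alone G2 and M phase genes stood at 0.27 in Cdk2-WT and 0.20 in Cdk2-Y15S.

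Heterozygous germ cells lay close to wild type in the spermatogonial lists, though not in every list or gene. Under the loose filter (115 Cdk2-WT, 61 Cdk2-HET and 110 Cdk2-Y15S cells), Stra8 was at 37.4 CPM, Lmo1 at 45.1, Bcl6b at 94.2, Mmp9 at 126 and Pmaip1 at 199 in Cdk2-HET. Their log2 ratios of Cdk2-HET over Cdk2-WT in these cells were 0.50, 0.41, -0.27, -0.06 and 0.16. Other genes lay further from wild type, with Tead2 (0.99), Lin28a (0.73) and Igfbp2 (0.71) shifted as in Cdk2-Y15S and Sox2 (0.84) the other way. Relative to Cdk2-WT, Cdk2-HET had list medians of -0.17 (-0.32 to -0.02) for undifferentiated, -0.09 (-0.18 to 0.35) for differentiating, -0.05 for piRNA, 0.17 for pluripotency and 0.07 for G2 and M phase genes. Set against Cdk2-HET instead, Cdk2-Y15S had -0.55, 0.32 (0.08 to 0.98), -0.51, -1.37 and 0.55 for the same lists. The SD of log2 ratios over genes with at least 200 UMIs was 0.261 for Cdk2-HET over Cdk2-WT, 0.515 for Cdk2-Y15S over Cdk2-WT and 0.496 for Cdk2-Y15S over Cdk2-HET. In Cdk2-HET germ cells extracellular matrix genes (0.68, 0.33 to 0.92), Sertoli niche genes (0.28, 0.03 to 0.58) and glycolysis (0.27, 0.02 to 0.39) were higher and mitochondrially encoded genes lower (-0.215, -0.245 to -0.186). Ambient RNA was not subtracted for Cdk2-HET, so RNA of somatic cells in these droplets cannot be told apart from expression by the germ cells. Under the fixed 10% limit (53, 34 and 62 cells) the Cdk2-HET medians were -0.08, -0.14 and -0.10 for undifferentiated, differentiating and piRNA genes, with intervals that include 0.

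**Figure D3:**
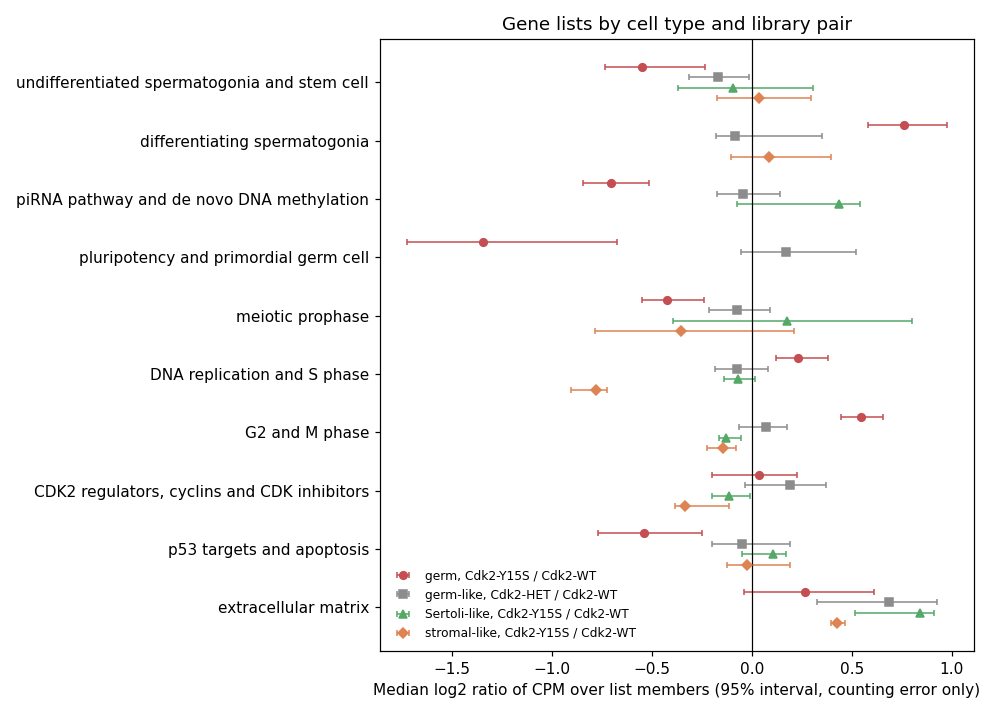
Median log2 ratio of CPM (x axis) of 10 gene lists (y axis), with 95% intervals for counting error, for germ cells of Cdk2-Y15S and Cdk2-HET against Cdk2-WT and for Sertoli cell-like and stromal cells of Cdk2-Y15S against Cdk2-WT. The differentiating list lies at 0.76 in Cdk2-Y15S and -0.09 in Cdk2-HET germ cells, and the S phase list at -0.78 in Cdk2-Y15S stromal cells.

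Sertoli cell-like cells made up less of the kept cells of the Cdk2-Y15S library and interstitial stromal cells more. Sertoli cell-like cells were 40.6% (39.2 to 42.0), 37.2% (35.9 to 38.6) and 33.4% (32.0 to 34.9) of kept Cdk2-WT, Cdk2-HET and Cdk2-Y15S cells, and 45.8%, 41.3% and 36.2% of the named somatic cells. Stromal cells were 34.4%, 37.1% and 40.9% of the named somatic cells and peritubular myoid cells 16.96%, 18.8% and 19.3%. Of the kept cells, fetal Leydig cells were 1.24%, 1.16% and 1.82% (59, 55 and 76 cells), endothelial cells 0.566%, 0.716% and 1.03%, macrophages 0.378%, 0.568% and 0.335%, and pericytes 0.294%, 0.189% and 0.263%. Unnamed clusters held 10.3%, 9.03% and 6.08%, and counting the largest of them, which leans to Sertoli genes, as Sertoli cell-like gave 50.3%, 45.04% and 39.7% of somatic cells. Under the strict filter (at least 1000 genes, at most 5% mitochondrial UMIs) the Sertoli shares of somatic cells were 20.9%, 23.96% and 9.41%, with Cdk2-HET above Cdk2-WT.

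Sertoli cell-like cells of Cdk2-Y15S had less RNA of the secreted Ptgds and Amh. Ptgds was at 373 CPM against 983 in Cdk2-WT (log2 -1.40; Cdk2-HET -0.46) and Amh at 426 against 824 (-0.95; Cdk2-HET 0.11). The niche list stood at -0.17 (-0.19 to -0.12). Rprm was lower in both mutants (28.7 CPM in Cdk2-WT, 1.68 in Cdk2-HET, 1.08 in Cdk2-Y15S) and Sh3bgr higher in both (2.58, 26.6 and 38.7). AA467197 (98.9, 84.2 and 7.34) and Spata21 (53.9, 50.9 and 4.79) were low in Cdk2-Y15S alone. Gchfr went from 0.161 CPM in Cdk2-WT (2 UMIs) to 100 in Cdk2-Y15S (1026 UMIs), a log2 ratio of 8.96 (7.43 to 12.33). Of the 8 Sertoli cell-like clusters, 1 held 730, 649 and 63 cells of Cdk2-WT, Cdk2-HET and Cdk2-Y15S and another 3, 30 and 448, so the values above compare partly different clusters.

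Extracellular matrix genes were mostly higher in the 3 large somatic classes of Cdk2-Y15S (18 of 18, 18 of 19 and 16 of 18 members above 0), with medians of 0.84 (0.52 to 0.91) in Sertoli cell-like, 0.43 (0.40 to 0.46) in stromal and 0.27 (0.21 to 0.34) in myoid cells, and of 0.54, 0.17 and 0.32 in Cdk2-HET. Postn in stromal cells was at 9.62, 21.05 and 56.6 CPM in Cdk2-WT, Cdk2-HET and Cdk2-Y15S and Lum at 67.1, 99.7 and 130. Eln in myoid cells was at 182, 213 and 333 CPM, Tnnt2 at 84.2, 135 and 242, and Col1a1 at 513, 696 and 788. In Sertoli cell-like cells Col1a1 (12.2, 21.6 and 27.5 CPM) and Lama2 (1.85, 4.33 and 4.21) had the highest ratios.

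Replication genes were lower in the Y15S stroma, unlike in its germ cells, and cluster makeup differed as well: a stromal cluster with Birc5 and Tcf19 among its top genes held 282 of 1454 Cdk2-WT, 296 of 1589 Cdk2-HET and 176 of 1579 Cdk2-Y15S stromal cells, and a myoid cluster with Mxd3 held 193 of 716, 182 of 805 and 128 of 744 myoid cells. The S phase list stood at -0.78 (-0.91 to -0.73; 0 of 24 members above 0) in stromal and -0.63 (-0.78 to -0.57) in myoid cells, and at -0.45 and -0.24 in Cdk2-HET. Sertoli cell-like cells stood at -0.07 (-0.14 to 0.01). In stromal cells Pcna was at 30.3, 22.2 and 8.05 CPM, Mcm5 at 47.4, 30.5 and 20.6, and the CDK2 cyclins Ccne1 at 23.4, 13.9 and 10.3 and Ccne2 at 14.4, 8.93 and 6.93. CDK2 regulators as a list lay at -0.34 in stromal, -0.32 in myoid and -0.11 in Sertoli cell-like cells. In myoid cells Pcna (-1.85), Cdc6 (-1.21) and Hist1h1b (-1.42) were lower. G2 and M phase genes were at -0.13, -0.15 and -0.11 in Sertoli cell-like, stromal and myoid cells of Cdk2-Y15S but at 0.15, 0.34 and 0.39 in Cdk2-HET.

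Most sterol synthesis genes were lower in the mesenchyme of both mutants. Cholesterol genes stood at -0.61 (-0.67 to -0.48; 0 of 17 above 0) in stromal and -0.30 (-0.42 to -0.15) in myoid cells of Cdk2-Y15S, and at -0.37 and -0.39 in Cdk2-HET. Sqle in stromal cells was at 113, 77.3 and 58.1 CPM and Dhcr7 at 37.7, 23.0 and 19.1, and in myoid cells Fdps stood at -0.54. Sertoli cell-like cells stood at -0.03 (-0.12 to 0.10), with Hmgcs1 higher (1.06). Fetal Leydig cells are below the fixed 200 cells, and their steroidogenic list, read outside that rule, was at -0.92 (-1.18 to -0.77) in Cdk2-Y15S and 0.07 in Cdk2-HET. Their cholesterol genes went the other way from those of the mesenchyme in Cdk2-HET, at 0.53 (0.39 to 0.77, with 16 of 17 above 0). In Cdk2-Y15S they stood at 0.21 (-0.10 to 0.34), with 9 members above 0 and 8 below.

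Other lists in Sertoli cell-like, stromal and myoid cells of Cdk2-Y15S stood at -0.21, -0.27 and -0.24 for glycolysis, -0.32, -0.08 and -0.38 for immediate early genes, 0.07, 0.08 and 0.04 for mitochondrially encoded genes and 0.10, -0.02 and 0.10 for p53 targets. In stromal and myoid cells the niche list stood at -0.06 and -0.48, and in the 3 classes steroidogenesis was at -0.28, -0.02 and 0.11 and retinoid signalling at 0.17, 0.04 and 0.04. Fos in Sertoli cell-like cells was at 718, 292 and 354 CPM and Phlda3 at 24.3, 49.9 and 61.6. Only 3 genes with at least 200 UMIs in each class were at least 2-fold apart the same way in all 3 classes. They were Rpl29 (16.8, 18.04 and 17.8-fold higher in Cdk2-Y15S, chromosome 9), Oser1 (2.81, 2.49 and 2.42-fold lower, chromosome 2) and the ribosomal RNA-derived AY036118 (2.47, 2.35 and 2.09-fold higher, chromosome 17). Gchfr, below that minimum in stromal and myoid cells, was also higher there in Cdk2-Y15S (38 and 15 UMIs, against 1 and 0 in Cdk2-WT). Rpl29 has many near-identical copies, so its value is uncertain.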

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

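No test in this part was chosen after the results were seen, and each value sets a list median of germ cells beside that of a somatic class in which the same list lies on the other side of 0. Cdk2-Y15S germ cells had higher G2 and M phase genes than Cdk2-WT (0.54), while Sertoli cell-like cells (-0.13) and stromal cells (-0.15) had lower ones, though with clusters B and C weighted equally the germ value was -0.30. S phase genes stood at 0.23 in germ cells, at -0.78 in stromal and at -0.63 in myoid cells, with a germ value of 0.016 when B and C were weighted equally and 0.90 in the rebuilt clusters. Immediate early and heat shock genes, which respond to dissociation, stood at 0.21 in germ cells, -0.32 in Sertoli cell-like cells and -0.38 in myoid cells. Mitochondrially encoded genes stood at -0.11 in germ cells, 0.069 in Sertoli cell-like cells and 0.078 in stromal cells, but this opposition is not stable: the germ value was 0.33 in the rebuilt germ cell-like clusters and the Sertoli value -0.00894 after scaling by the median ratio. What drew attention in each case is the opposite sign under the same contrast, and the difference was not tested, since each genotype has 1 library.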

How the results depend on the processing

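Settings chosen after the data were seen are the unnamed cluster, the loose filter for germ lists and the removal of chromosome 2 genes. No paired analysis was possible because each genotype has 1 library, and for the same reason no library could be left out in turn. Of the values under other settings for results whose interval lies off 0, 116 of 120 for germ lists, 569 of 584 for germ genes, 9 of 9 for heterozygous germ lists and 271 of 273 for somatic lists and genes kept their sign. These tallies pool unlike settings: all 17 germ lists stayed within their intervals when thinned or scaled by the median ratio. With clusters B and C weighted equally, 11 germ lists left their intervals and 3 more reversed. Of the 93 germ genes, 49 left their intervals and 10 more reversed. Where values differ, the cause was not tested. With at least 200 genes and at most 20% mitochondrial UMIs the germ shares of Cdk2-WT, Cdk2-HET and Cdk2-Y15S were 2.32%, 1.26% and 2.54%, and the Sertoli cell-like shares of named somatic cells 50.3%, 43.9% and 40.03%. With at least 1000 genes and at most 5% mitochondrial UMIs the Sertoli shares were 20.9%, 23.96% and 9.41%, so the heterozygote no longer lay below the wild type, and the germ shares were 0.959%, 0.676% and 0.852%, with Cdk2-Y15S below Cdk2-WT and overlapping intervals. At resolution 0.5 the Cdk2-Y15S Sertoli share was 38.3%. Adding the unnamed cluster gave 50.3%, 45.04% and 39.7%, with Sertoli medians of -0.14 for S phase and 0.91 for extracellular matrix genes. Of germ cells that pass the filter 78.9% sat in clusters of 1 library, and of germ cells clustered without chromosome 2 genes 100%. Clustered again in the same way with all genes, 61.7% did, and without the cell cycle lists 70.2%. Leaving out the single gene Amh also gave 100%.

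Clusters B and C weighted equally leave out clusters A, D and E and rest on as few as 5 cells. The medians were then 0.56 for differentiating, -0.054 for piRNA, -0.067 for pluripotency, -0.19 for meiotic, 0.016 for S phase and -0.27 for CDK2 regulator genes. The sign reversed for G2 and M phase genes (-0.30), p53 targets (0.41), mitochondrially encoded genes (0.073), Aurkb (-0.19), Cdk6 (-0.37), Cdkn1a (0.63), Dnmt3l (1.17), Gapdh (-0.32), Nanos3 (-1.58), Rxrb (0.026), Ube2c (-0.22), Zmat3 (0.76) and mt-Co1 (0.12). In the rebuilt germ cell-like clusters the medians were -0.38 for pluripotency, -0.17 for meiotic, 0.90 for S phase, 1.10 for G2 and M phase and 0.43 for CDK2 regulator genes. Signs reversed there for mitochondrially encoded genes (0.33), Insig1 (0.018), Scarb1 (-0.023), Uhrf1 (0.31) and mt-Co1 (0.022). Under the loose filter the S phase median was 0.40. Pluripotency members with at least 50 UMIs gave -0.13. Subtracting 10% ambient RNA reversed Col3a1 in germ cells (-0.21). Scaling by the median ratio gave -0.15 for S phase genes and -0.00894 for mitochondrially encoded genes in Sertoli cell-like cells, the latter reversed. Leaving out chromosome 2 genes gave 0.50 for the stromal extracellular matrix list. Thinning cells to 3000 UMIs gave 0.014 for CDK2 regulators in myoid cells, where the sign reversed.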

Other observations

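All tests in this part were chosen after the results were seen. Rpl21 was far lower in the heterozygote than in either other library, at 1036, 36.3 and 755 CPM in Sertoli cell-like cells of Cdk2-WT, Cdk2-HET and Cdk2-Y15S, 1134, 49.01 and 896 in stromal cells and 766, 23.2 and 680 in germ cell-like cells. Hist1h2ak was at 44.6, 1.60 and 65.7 CPM in Sertoli cell-like cells. Both genes were picked after their values were seen and have near-identical copies. Among the 50 genes with the largest Cdk2-Y15S ratios, chromosome 2 held 13 in Sertoli cell-like, 11 in stromal, 4 in myoid and 3 in germ cells, while it holds 8.14% of the genes compared in Sertoli cell-like cells. Chromosome 10, which carries Cdk2, held 1, 0, 2 and 3.

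Germ cell lists and clusters lay apart between Cdk2-Y15S and Cdk2-WT, and the substitution, strain variants, a shift of the whole library or differences between animals could each lie behind it. For strain variants that alter the counts of chromosome 2 genes themselves, these genes were left out. The 7 lists with an interval off 0 and members there kept their signs, with pluripotency at -1.32 and S phase at 0.32. Most members lie elsewhere (17 of 19 undifferentiated and 16 of 22 G2 and M phase genes), so the medians could move little. Chromosome 2 also held 3 of the 50 largest germ ratios, with 7.39% of the genes compared. The list medians do not rest on the counts of chromosome 2 genes. Variants on other chromosomes and effects of any variant on genes elsewhere stay open. Clustering without chromosome 2 genes left 100% of germ cells in clusters of 1 library, against 61.7% with all genes. The share in such clusters sits on the edge of the 90% rule and ranged from 61.0% to 100% when each of the 19 autosomes was left out. Without the single gene Amh it was also 100%, so it does not decide on chromosome 2. A shift of the whole library is argued against for genes that Sertoli cell-like cells also express. Of 253 germ genes at least 2-fold apart, 200 had at least 200 UMIs in Sertoli cell-like cells. Signed by the germ direction, the median log2 ratio of these 200 genes there was -0.062. Genes nearly absent from Sertoli cell-like cells, such as Stra8 and Bcl6b, are not covered, so for them the question stays open. Age, litter or other differences between animals cannot be told apart from the substitution with 1 library per genotype.

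Sertoli cell-like cells split by library, with 32.1% of the Cdk2-Y15S ones in clusters at least 80% of that library, and variants of a few genes or depth might account for it. Chromosome 2 was left out first, which took the 32.1% to 0%. Each of the 19 autosomes followed, of which chromosome 9 also gave 0% and the other 17 gave 29.6% to 37.4%. The single genes Rpl29, Gchfr and Amh were left out last. A cluster just under the 80% limit is not counted, so 0% does not show that the split was gone. Leaving out the difference of 1 gene, Rpl29, gave 0%, and leaving out the difference of 1 gene, Gchfr, also gave 0%, while leaving out Amh gave 32.1%. The clusters above that limit may thus rest on both Rpl29 and Gchfr. Gchfr was higher in Cdk2-Y15S than in Cdk2-WT in Sertoli cell-like, stromal (38 and 1 UMIs) and myoid cells (15 and 0 UMIs). It did not differ between Cdk2-WT and Cdk2-Y15S germ cells (12.2 and 16.8 CPM with overlapping intervals). A difference in depth is argued against, since the median UMIs of the 2 clusters stood at a ratio of 0.9898. Rpl29 lies on chromosome 9 and Gchfr on chromosome 2, while Cdk2 lies on chromosome 10, so neither gene is linked to the Cdk2 allele. In Sertoli cell-like cells of Cdk2-WT, Cdk2-HET and Cdk2-Y15S, Rpl29 was at 25.8, 28.6 and 434 CPM. Gchfr was at 0.161, 0.401 and 100 CPM, so the heterozygote lay near the wild type for both. Whether they differ through the allele, unlinked strain variants or the animal stays open.

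The extracellular matrix list was higher in Cdk2-Y15S Sertoli cell-like cells, and stromal RNA in their droplets or expression by the cells themselves could produce it. The 12 members at least 10-fold higher in stromal cells, among them Col1a1, Col3a1, Dcn and Lum, had a median of 0.94 (0.77 to 1.14) against 0.69 in the whole libraries, and for these stromal RNA and Sertoli expression cannot be told apart. The other 6 members, Col4a1, Col4a2, Lamb1, Lamc1, Fbn1 and Sparc, had a median of 0.37 (0.29 to 0.47), close to 0.39 in the whole libraries. They stood at a median of 45.3% of the stromal level in Cdk2-WT (lowest 16.7%), against 1.31% for the 12. The 10-fold split itself puts the 6 above the 12 in this share, so that order is no evidence. If stromal RNA reaches all genes alike, the share of the 12 falls short of the level of the 6. This argues against stromal RNA as the main source of that level, but the ratio of the 6 does not tell the 2 explanations apart. Sparc was at 1475, 1790 and 1887 CPM in Cdk2-WT, Cdk2-HET and Cdk2-Y15S.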
